A study of Arabidopsis thaliana with 12 samples.

How the data were processed

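The series holds 12 RNA sequencing libraries of Arabidopsis thaliana seeds, 3 of each genotype (Col-0 and erf4-1) in each of 2 states, dry and imbibed for 6 h. Each library was put in its group by its own label. The groups share the replicate numbers 1 to 3.

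The authors deposited 1 table of raw counts per gene, in whole numbers, laid out as featureCounts writes it, with gene coordinates and exonic lengths per the file headers. Per the submitters' processing notes the tools were fastp 0.20.0, HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 1.34.0, and the build was TAIR10. Their parameters, the strand setting and the annotation release were not given in the sources used here. Reads from a gene and its partner on the other strand could therefore not be told apart, and such genes are marked as uncertain, as are genes with a near copy. The table lists 32833 genes, of which 32548 are nuclear and 285 of the organelles. All 32548 nuclear identifiers matched the reference annotation, 32532 of them (99.95%) with the same start and end, and 10804 genes have a symbol. Every count column belonged to a sample, and every line named a gene.

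Total counts ranged from 31787283 to 42590777 per library. The 10 most abundant genes took 15.3 to 26.9% of a library and organelle genes 0.013 to 0.067%. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group correlated at r = 0.958 to 0.983 on the log2 scale, across genes. Their counts differed by a chi-square of 20.5 to 157.5 per degree of freedom, so that no library was taken for a repeat of another. The first principal component, which parted dry from imbibed seeds, took 64.5% of the variance.

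Genes with low counts were removed by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 18897 genes with 99.97% of the counts. Libraries were scaled by TMM factors, and CPM values are TMM-scaled. All 12 libraries entered 1 quasi-likelihood model of the 4 group means (robust fit, 8 residual degrees of freedom, biological coefficient of variation 0.241). Each contrast was tested by edgeR's quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The contrasts were libraries labelled erf4 against Col-0 in dry and in imbibed seeds, imbibed against dry seeds in each genotype, and the difference between the 2 genotype contrasts. Log2 fold changes are given with their standard errors, group levels as mean ± SD, and the prior count for log2 CPM was 2. For a gene without a count in a group, the fold is a lower bound against 3 counts over that group. Overlaps of calls were tested by a one-sided Fisher's exact test.

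Before the data were examined, 23 gene lists with 792 entries were fixed. They cover ABA synthesis and catabolism, ABA signalling, dormancy, gibberellin, ethylene, other ERF factors, storage proteins, LEA proteins, seed maturation, heat shock, seed coat mucilage, cell wall loosening, flavonoids, jasmonate, reactive oxygen enzymes, iron, lipid mobilisation, cell cycle, photosynthesis, endosperm, light, the circadian clock and ribosomal proteins. The ribosomal list of 324 entries was taken from the annotation's descriptions and may hold a few organellar members. A further entry, ACO3, was left out because its symbol resolved to an aconitase. Only 2 genes stand in more than 1 fixed list. A list of 44 pollen and tapetum markers was written after the most changed genes had been seen, and 13 of its members came from those genes. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the fixed lists within a contrast, and again with an estimated correlation.

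The genes named were set by a rule, except where stated otherwise. It took ERF4 and its neighbours, and the 8 largest rises and falls of each genotype contrast, 6 of each imbibition contrast and 4 of the interaction, with an adjusted p under 0.05. A mean of at least 1 CPM in the higher group was required and, except for the interaction, no overlap between the groups. It also took up to 4 called or 2 uncalled members of each list, and DOG1, ABI5 and CAT3 whatever their values. Copies are genes that share at least 95% identity over at least 100 bp in BLAST 2.17.0.

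Alternatives fixed beforehand were RLE size factors, no filter or a filter of 1 CPM in 6 libraries, nuclear genes only, the replicate number as a block, the suffix letter of the library names as a covariate, and only the groups compared. The suffix letter was r in all imbibed libraries and b or r in the dry ones, so it was partly tied to the seed state. Leaving out each library, DESeq2 1.42.0, an adjusted p under 0.01 and a log2 fold change of at least 1 were fixed too. Alternatives chosen after seeing the data left out both libraries labelled erf4 of 1 number, set a block within each genotype, or averaged the genotype difference over both states. Whether the numbers pair the libraries was checked by the correlation, across genes, of same-numbered deviations from the group means. It was 0.34, 0.34 and 0.35 between dry and imbibed libraries labelled erf4, and at most -0.17, -0.14 and -0.11 with another number. The 3 deviations of a group sum to 0, so a positive value with the own number holds the others low. The negative values are therefore no separate evidence. From the own-number values the numbers were taken to pair these libraries, a reading of the data and not of the labels. Between the genotypes the correlation was 0.07, -0.17 and -0.28 in dry seeds and 0.08, -0.11 and -0.24 in imbibed seeds. There Col-0 replicate 3 reached 0.35 (dry) and 0.34 (imbibed) with another number, so an r of that size alone does not show pairing.

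The model was tested on simulated counts with 100 genes changed by a log2 fold change of 1 and 100 by 2. In dry seeds 48 and 80% were recovered among 18556 genes, and in imbibed seeds 46 and 72% among 18404. For imbibition they were 37 and 71% in Col-0 (18545 genes) and 60 and 71% in libraries labelled erf4 (18372 genes), and for the interaction 16 and 69% (18342 genes). False calls numbered 7, 3, 6, 8 and 9. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.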

Results

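Gene expression was measured by RNA sequencing in seeds of Arabidopsis thaliana accession Col-0, the wild type, and of the mutant erf4-1. ERF4 is an ethylene response factor of the AP2/ERF family with a repressor motif. The seeds were freshly harvested, a stage at which seeds of this species are usually dormant, and were sampled either dry or after 6 h of imbibition (water uptake) on wet filter paper. The 12 libraries formed 4 groups of 3, and the design compared the genotypes in each seed state, the seed states in each genotype, and the genotype difference between the states. Total gene counts were 37078043, 41820266 and 36960635 in dry Col-0 and 42590777, 31787283 and 35304170 in the dry libraries labelled erf4. They were 34283710, 35933334 and 37905048 in imbibed Col-0, and 38245860, 38157372 and 38398080 in the imbibed libraries labelled erf4. At these depths 3 counts in a library corresponded to 0.070 to 0.094 CPM (the count scaled to the library's total counts), before TMM scaling. The CPM levels below are TMM-scaled. CRA1, which encodes a cruciferin storage protein, alone took 5.25 to 9.29% of the counts of a library. The labels do not say whether replicates came from separate plants or harvests, so p-values measure only the spread between these samples, which may be technical.

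ERF4 itself was examined first, in every library. The gene (AT3G15210) lies on chromosome 3 at 5121303 to 5122562 on the plus strand of TAIR10 and has 1 exon of 1260 bp. It had 511, 471 and 343 counts in dry Col-0 (14.0 ± 1.72 CPM, SD, n = 3) and 839, 664 and 689 counts in imbibed Col-0 (17.9 ± 2.78 CPM). In the dry libraries labelled erf4 it stood at 3.88, 9.0 and 15.28 CPM, which is 27.7%, 64.3% and 109.0% of the dry Col-0 mean. In the imbibed libraries labelled erf4 it stood at 1.67, 7.03 and 14.91 CPM, or 9.3%, 39.2% and 83.3% of the imbibed Col-0 mean. ERF4 transcript in the libraries labelled erf4 replicate 3 therefore goes against the label, and every direction given for the mutant below rests on the labels and not on the ERF4 level. The group difference was not called in dry seeds (log2 fold change -0.58 ± 0.61 SE, n = 3 per group, edgeR adjusted p = 0.691) or in imbibed seeds (-1.18 ± 0.61, edgeR adjusted p = 0.387). Of the genes beside it, AT3G15200 (5117489 to 5119060, minus strand, overlapping a gene on the other strand) differed by 0.52 ± 0.19 in dry seeds (edgeR adjusted p = 0.208) and by 0.57 ± 0.19 in imbibed seeds (edgeR adjusted p = 0.212). The gene on the other side, AT3G03035 (5125409 to 5126398), had too few counts to be tested.

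**Figure D1:**
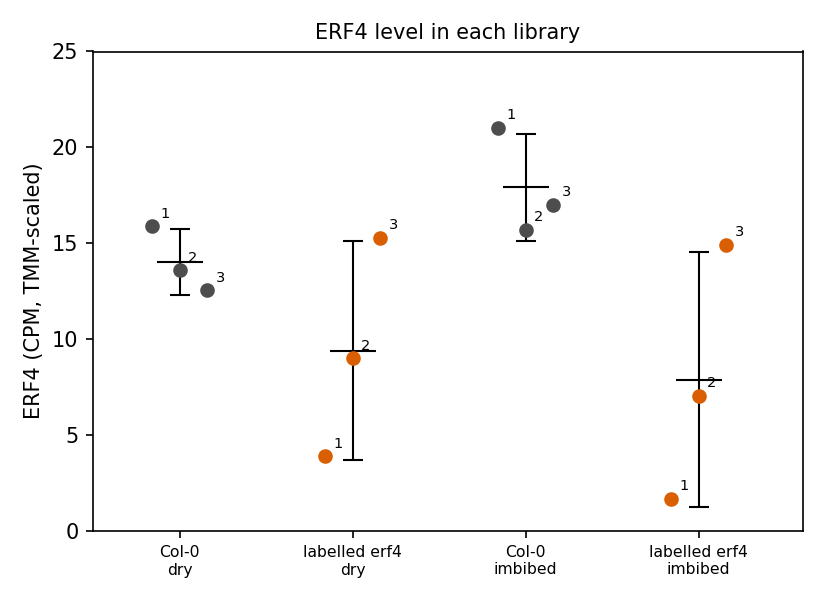
ERF4 level in TMM-scaled CPM (vertical axis) in each of the 12 libraries (points, numbered by replicate) by group (horizontal axis), with the group mean and SD (bars). The libraries labelled erf4 replicate 1 lie at 3.88 and 1.67 CPM, and those labelled erf4 replicate 3 at 15.28 and 14.91 CPM, close to the Col-0 libraries.

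The first comparison asked which transcripts differed between the genotypes in dry seeds. Transcripts known from pollen were lower in the libraries labelled erf4, a direction that follows the labels although ERF4 goes against them in replicate 3. The multicopper-oxidase-like gene sks13 fell from 100.4 ± 27.7 CPM (SD, n = 3) in Col-0 to 14.4 ± 5.07 CPM (log2 fold change -2.79 ± 0.32 SE, edgeR adjusted p = 0.00465). VGD1, a pectin methylesterase gene of pollen tube growth, fell from 68.0 ± 22.6 to 9.36 ± 4.34 CPM (-2.85 ± 0.33, edgeR adjusted p = 0.00465). Among the higher transcripts, RPL18AA, annotated as a ribosomal protein gene, rose from 5.06 ± 0.307 to 45.8 ± 9.38 CPM (3.18 ± 0.19, edgeR adjusted p = 4.39e-06). AT1G75945, an uncharacterised protein gene, had no count in any dry Col-0 library and 6.19 ± 1.74 CPM in libraries labelled erf4. This was at least 186.8-fold higher against a floor of 3 counts over the Col-0 group (edgeR adjusted p = 0.000131). The seed catalase gene CAT1 fell from 230.1 ± 46.4 to 121.8 ± 26.3 CPM (-0.92 ± 0.18, edgeR adjusted p = 0.0329).

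By the rule for naming genes, the other rises named by size were those of AT4G13577 (3.94 ± 0.78), the calmodulin-like gene CML43 (3.71 ± 0.79), the signal recognition particle RNA gene AT7SL-1 (2.67 ± 0.47), the dehydrin gene AT1G54410 (2.48 ± 0.39), AT5G48500 (2.32 ± 0.45) and AT3G29280 (2.23 ± 0.44). Their edgeR adjusted p lay between 0.00991 and 0.0425. AT7SL-1 shares 702 bp with its copy EVE1, and AT3G29280 overlaps a gene on the other strand. Reads of these 2 genes could therefore be split or shared. The largest falls were those of the SAUR-like gene AT3G20220 (-3.50 ± 0.64), the beta-glucosidase gene BGLU15 (-3.34 ± 0.68) and the beta-galactosidase gene BGAL11 (-3.28 ± 0.45, from 27.0 ± 6.74 to 2.75 ± 1.61 CPM). They were followed by the cation/proton exchanger gene CHX23 (-3.26 ± 0.44), the carboxypeptidase-like gene scpl38 (-3.25 ± 0.59), and the pectin methylesterase inhibitor family gene AT2G47050 (-3.21 ± 0.56). Next came the ENTH/VHS-domain gene AT1G03050 (-3.18 ± 0.40) and the arabinogalactan peptide gene AGP23 (-3.17 ± 0.51, from 57.0 ± 23.1 to 6.25 ± 4.31 CPM). Their edgeR adjusted p lay between 0.00483 and 0.0346, and AT3G20220 and AT1G03050 overlap genes on the other strand. DOG1, the central regulator of seed dormancy, stood at 53.1 ± 9.76 and 30.6 ± 5.1 CPM (-0.80 ± 0.20) and was not called (edgeR adjusted p = 0.0742). It was called by DESeq2 (adjusted p = 0.0122) and without imbibed Col-0 replicate 3 (edgeR adjusted p = 0.049), with adjusted p between 0.0122 and 0.228 over the alternatives. ABI5, a transcription factor of abscisic acid (ABA) responses in seeds, differed by 0.18 ± 0.24 (edgeR adjusted p = 0.755) and the catalase gene CAT3 by -0.10 ± 0.16 (edgeR adjusted p = 0.823).

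In all, 207 of 18897 genes were called in dry seeds, 98 higher and 109 lower in libraries labelled erf4 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these, 136 differed at least 2-fold. The count was 41, 81 or 56 without dry Col-0 replicate 1, 2 or 3, 80 without the dry library labelled erf4 replicate 3 and 129 without imbibed Col-0 replicate 2. It was 69 without both libraries labelled erf4 replicate 3, 384 without both of replicate 1 and 368 without both of replicate 2. DESeq2 called 936 genes, a fit on the 2 groups alone 114 (24 higher, 90 lower), and a fit with the suffix letter of the library names as a covariate 464.

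Of the gene lists, the pollen and tapetum markers moved most in dry seeds. This list was written after the most changed genes had been seen, and 13 of its 44 members were taken from those genes. Of its 36 tested members 19 fell and none rose (27 fell adjusted over the list alone), with a median log2 fold change of -2.48 (camera unadjusted p = 1.19e-46; 0.000168 with an estimated correlation). The 23 tested members not taken from those genes had a median of -1.56 (camera unadjusted p = 3.42e-18; 0.000378 with an estimated correlation). The markers summed to 668.1 ± 183.8 CPM in dry Col-0, 135.8 ± 37.3 CPM in the dry libraries labelled erf4, and 50.0 ± 1.7 and 47.5 ± 4.1 CPM in imbibed Col-0 and in the imbibed libraries labelled erf4 (SD, n = 3). Of the lists fixed beforehand, that of the ribosomal proteins had 25 members that rose and none that fell among 298 tested, or 92 and 3 adjusted over the list alone, with a median of 0.35 (camera adjusted p = 8.71e-23; call lost with adjusted p = 0.598 with an estimated correlation). AT2G37190, of the L11 family, rose from 46.5 ± 7.06 to 92.8 ± 8.75 CPM (1.00 ± 0.13, edgeR adjusted p = 0.00483).

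**Figure D2:**
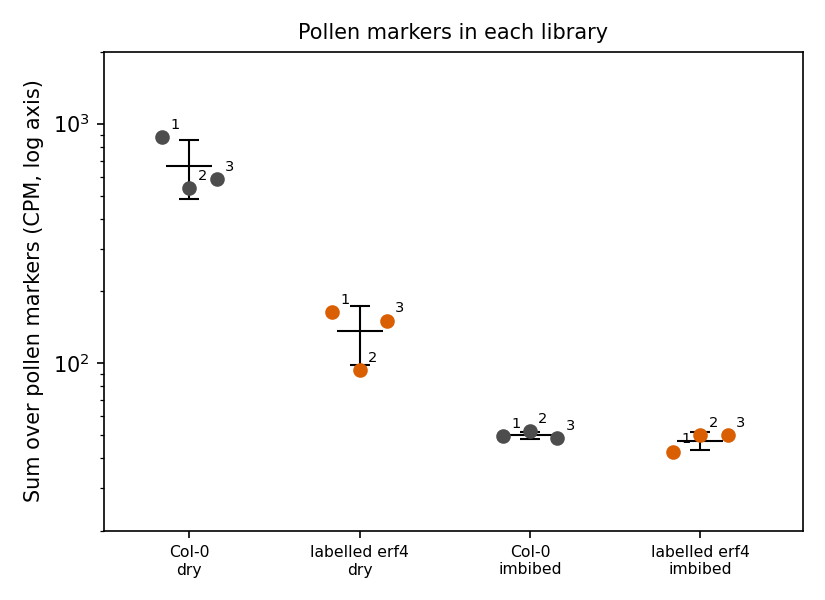
Sum of the pollen and tapetum markers in CPM (vertical log axis) in each of the 12 libraries (points, numbered by replicate) by group (horizontal axis), with the group mean and SD (bars). The dry Col-0 libraries lie between 539.0 and 878.6 CPM, the dry libraries labelled erf4 between 93.5 and 163.7 CPM and all imbibed libraries between 42.7 and 51.9 CPM.

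The other lists held few called members in dry seeds. The photosynthesis genes, which also mark green vegetative tissue, lay higher with 0 of 19 members called by edgeR, 6 at an unadjusted p under 0.05 and 3 by DESeq2 (3 rose adjusted over the list alone; median 0.48, camera adjusted p = 0.000506), and RBCS1A, of the Rubisco small subunit, stood at 46.3 ± 9.67 and 111.9 ± 59.8 CPM (edgeR adjusted p = 0.11). The lipid mobilisation genes lay lower with 0, 6 and 2 of 19 in the same order (2 fell adjusted over the list alone; median -0.20, camera adjusted p = 0.00865). Both calls were lost, each with adjusted p = 0.598 with an estimated correlation. The late embryogenesis abundant (LEA) protein genes (0, 6 and 1 of 17; none adjusted over the list alone; median 0.42) and the cell wall loosening genes (0, 6 and 2 of 23; 1 rose and 1 fell adjusted over the list alone; median 0.86, or 0.50 with genes absent from a group at their bound) lay higher, each with a camera adjusted p of 0.0364. These calls were lost too, each with adjusted p = 0.857 with an estimated correlation. Among the reactive oxygen enzymes CAT1 was called, 1 of 17, also adjusted over the list alone (camera adjusted p = 0.845, median 0.11, mean 0.17, test direction lower). The remaining 17 lists had no member called by edgeR over all genes and camera adjusted p between 0.133 and 0.889. Over all 18897 genes 2948 had an unadjusted p under 0.05 in dry seeds, where chance gives 945, and the list counts are to be read against that. At an unadjusted p under 0.05, and by DESeq2, the numbers of members were 6 and 2 for ABA signalling, 2 and 2 for ABA synthesis, 3 and 1 for cell cycle and 2 and 0 for the circadian clock. They were 3 and 2 for dormancy, 2 and 0 for endosperm, 4 and 0 for ethylene, 0 and 0 for flavonoids and 7 and 4 for gibberellin. For heat shock they were 2 and 0, for iron 1 and 1, for jasmonate 4 and 1 and for light 5 and 1. They were 4 and 0 for other ERF factors, 4 and 1 for seed coat mucilage, 3 and 3 for seed maturation and 3 and 0 for storage proteins. Adjusted over the list alone, 4 gibberellin genes rose and 1 fell, 2 dormancy genes fell, and in the other 15 lists at most 2 members did either. The median, the mean and the test did not share a sign for the clock, dormancy, endosperm, jasmonate and mucilage lists.

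The second comparison asked how the genotypes differed after 6 h of imbibition. Only 4 genes were called of 18897 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these 3 were higher in the libraries labelled erf4, by the labels, which ERF4 goes against in replicate 3. In all 2827 genes had an unadjusted p under 0.05 where chance gives 945. IRT3, a metal transporter of the ZIP family (chromosome 1, 22445299 to 22447299, minus strand), rose from 0.633 ± 0.159 to 36.7 ± 11.3 CPM (SD, n = 3; log2 fold change 5.85 ± 0.38 SE, edgeR adjusted p = 1.38e-05). AT1G75945 (chromosome 1, 28515245 to 28515916, minus strand) rose from 0.106 ± 0.0377 to 11.5 ± 4.95 CPM (6.72 ± 0.47, edgeR adjusted p = 6.82e-05), and RPL18AA (chromosome 1, 10498351 to 10501498, minus strand) from 2.77 ± 0.6 to 14.2 ± 1.49 CPM (2.36 ± 0.19, edgeR adjusted p = 6.82e-05). HEI10, a RING-domain gene of meiotic crossover formation (chromosome 1, 19963267 to 19966952, plus strand), fell from 13.3 ± 0.399 to 3.68 ± 0.386 CPM (-1.85 ± 0.19, edgeR adjusted p = 0.000927).

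Of these 4 genes, RPL18AA shares 1112 bp of its span with AT1G29965 on the same strand, which had 0 to 40 counts per library. AT1G29965 differed in the same direction as RPL18AA but was not called. Its log2 fold change was 5.49 in dry and 7.28 in imbibed seeds (edgeR adjusted p = 0.196 and 0.132). HEI10 overlaps MRD1 on the other strand (0 to 9 counts) and AT1G07887 on the same strand (0 counts), and 9 bp of MUM4 on the other strand (52 to 174 counts), so that reads of RPL18AA and HEI10 could be shared with these genes. All 4 kept their call and direction under every alternative of this comparison, including those without any one library and without both libraries of any 1 replicate labelled erf4. IRT3, looked up there after its values were seen, also rose in dry seeds (2.16, edgeR adjusted p = 0.0141). That call was lost without dry Col-0 replicate 3 (edgeR adjusted p = 0.0511), without both libraries labelled erf4 replicate 3 (0.0584) and on the 2 groups alone (0.0746), and its adjusted p ranged from 1.26e-06 to 0.0746 over the alternatives. DOG1 stood at 19.0 ± 5.73 and 11.2 ± 0.648 CPM (-0.76 ± 0.20, edgeR adjusted p = 0.15, between 0.0318 by DESeq2 and 0.461 over the alternatives), ABI5 differed by -0.55 ± 0.24 (edgeR adjusted p = 0.302) and CAT3 by -0.17 ± 0.16 (edgeR adjusted p = 0.652). The count of calls rose to 47 without the imbibed library labelled erf4 replicate 2 and to 386 without both libraries labelled erf4 replicate 2. It was 7 without dry Col-0 replicate 3, 10 without imbibed Col-0 replicate 2, 10 and 13 without the dry libraries labelled erf4 replicates 1 and 2, 18 with no filter on low counts, and 527 with DESeq2.

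**Figure D3:**
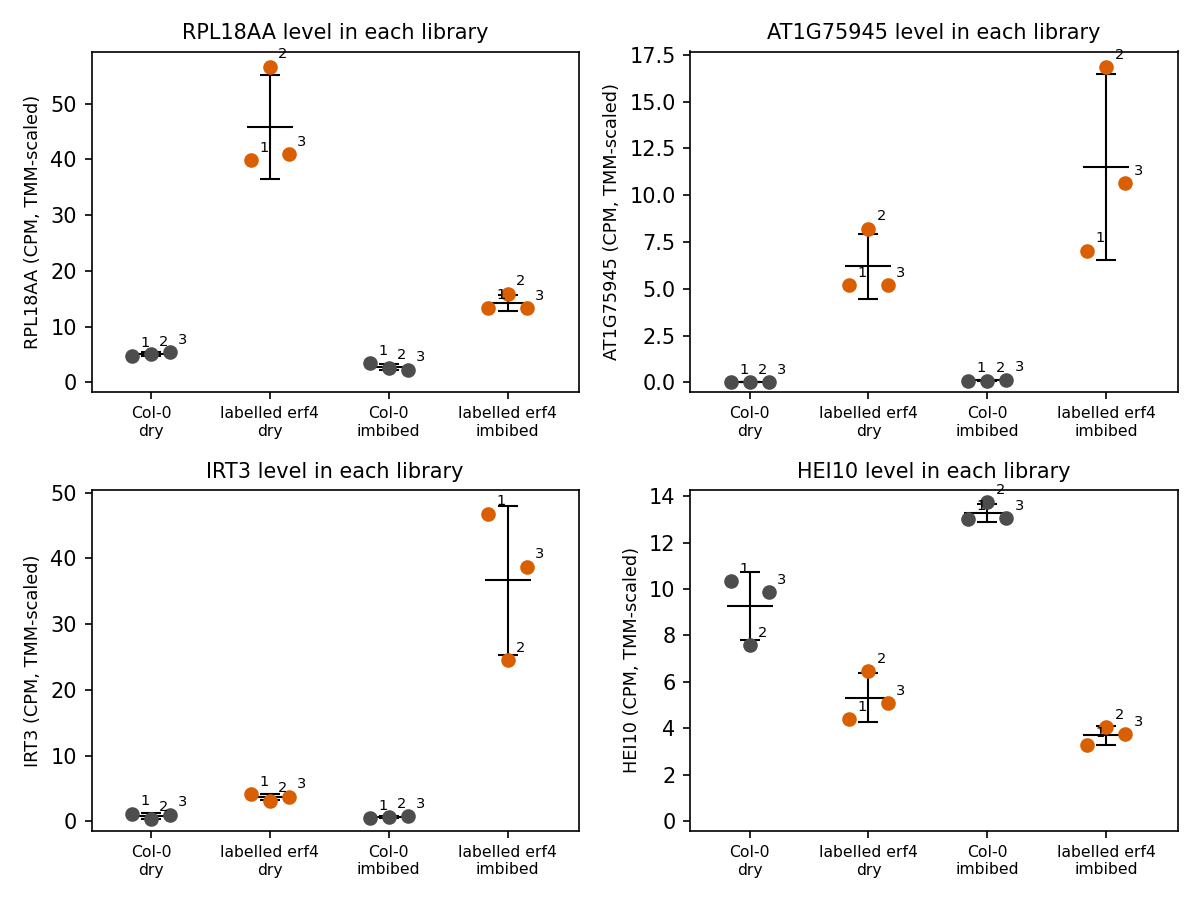
TMM-scaled CPM (vertical axes) of the 4 genes called in imbibed seeds in each of the 12 libraries (points, numbered by replicate) by group (horizontal axes), with the group mean and SD (bars). All 3 libraries labelled erf4 lie apart from all 3 Col-0 libraries in imbibed seeds, RPL18AA for example at 13.32 to 15.92 CPM against 2.27 to 3.43 CPM.

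Genes of heat shock and of ABA signalling lay lower as lists in imbibed seeds. The heat shock proteins and factors lay lower in the libraries labelled erf4. Of 20 tested members 11 fell adjusted over the list alone and 0 by edgeR over all genes, 14 had an unadjusted p under 0.05 and DESeq2 called 6. The median log2 fold change was -0.88 (camera adjusted p = 1.7e-11; adjusted p = 0.047 with an estimated correlation). With an estimated correlation this call was lost without both libraries labelled erf4 replicate 1, 2 or 3 (adjusted p = 0.151, 0.153 and 0.107). The chaperone gene HSP90.1 stood at 533.7 ± 144.2 CPM in Col-0 and 261.1 ± 38.6 CPM in libraries labelled erf4 (-1.03 ± 0.19, edgeR adjusted p = 0.0929), and HSP70 at 1677.8 ± 227.2 and 890.5 ± 125.4 CPM (-0.91 ± 0.17, edgeR adjusted p = 0.0941). The genes of ABA signalling and response also lay lower, with 8 of 31 that fell adjusted over the list alone, 0 by edgeR over all genes, 15 at an unadjusted p under 0.05 and 4 by DESeq2 (median -0.30, camera adjusted p = 7.93e-05; adjusted p = 0.0257 with an estimated correlation). This call too was lost with an estimated correlation without both libraries of replicate 1, 2 or 3 (adjusted p = 0.088, 0.118 and 0.0829). ABI2, a phosphatase that represses ABA signalling, stood at 27.7 ± 2.69 and 16.2 ± 2.02 CPM (-0.77 ± 0.13, edgeR adjusted p = 0.0787), and OST1, a kinase that transmits it, at 40.9 ± 4.04 and 24.6 ± 2.0 CPM (-0.73 ± 0.16, edgeR adjusted p = 0.117).

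Other lists passed camera with the preset correlation alone. Apart from RPL18AA no member of them was called by edgeR over all genes, while 2 to 36 members by list were called by DESeq2 or, for lipid mobilisation and photosynthesis, 1 each. The ribosomal proteins lay higher (1 rose of 298, 38 adjusted over the list alone, median 0.38, camera adjusted p = 3.75e-25; adjusted p = 0.22 with an estimated correlation). So did the cell wall loosening genes, the expansins and xyloglucan-modifying enzymes of growing walls (11 rose and 1 fell of 23 adjusted over the list alone, median 0.79, camera adjusted p = 2.67e-05; adjusted p = 0.289 with an estimated correlation). EXPA8 stood at 9.49 ± 2.78 and 21.8 ± 6.7 CPM (edgeR adjusted p = 0.137). The cell cycle genes (2 of 21 rose adjusted over the list alone, median 0.49, camera adjusted p = 0.000665) and the photosynthesis genes (0 of 19, median 0.43, camera adjusted p = 0.0102) lay higher too, with adjusted p = 0.22 and adjusted p = 0.389 with an estimated correlation. The LEA proteins (4 of 17 fell adjusted over the list alone, median -0.55, camera adjusted p = 7.93e-05) and the ethylene genes (3 of 22, median -0.28, camera adjusted p = 0.00172) lay lower, each with adjusted p = 0.223 with an estimated correlation. Lower too were ABA synthesis and catabolism (2 of 13 fell adjusted over the list alone, median -0.33, camera adjusted p = 0.00626; adjusted p = 0.22 with an estimated correlation) and lipid mobilisation (0 of 19, median -0.22, camera adjusted p = 0.00307; adjusted p = 0.243 with an estimated correlation). The storage proteins, the main reserve of the seed, lay lower (4 of 16 fell and 1 rose adjusted over the list alone, median -0.56, camera adjusted p = 0.0102; adjusted p = 0.504 with an estimated correlation), although CRU2 stood at 644.2 ± 157.8 and 1227.1 ± 116.4 CPM (0.93 ± 0.19, edgeR adjusted p = 0.117). The remaining 12 fixed lists had no member called by edgeR over all genes, 0 to 7 members at an unadjusted p under 0.05, 0 to 3 by DESeq2, and camera adjusted p between 0.0608, for the dormancy regulators, and 0.723. Adjusted over the list alone, 5 seed maturation genes rose and 3 dormancy genes fell, and at most 2 members of the other 10 lists did either. The pollen and tapetum markers had 0 of 36 called by edgeR, 2 at an unadjusted p under 0.05 and 0 by DESeq2 (median -0.18, mean 0.03, camera unadjusted p = 0.457). The median, the mean and the test did not share a sign for the flavonoid, endosperm and mucilage lists.

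**Figure D4:**
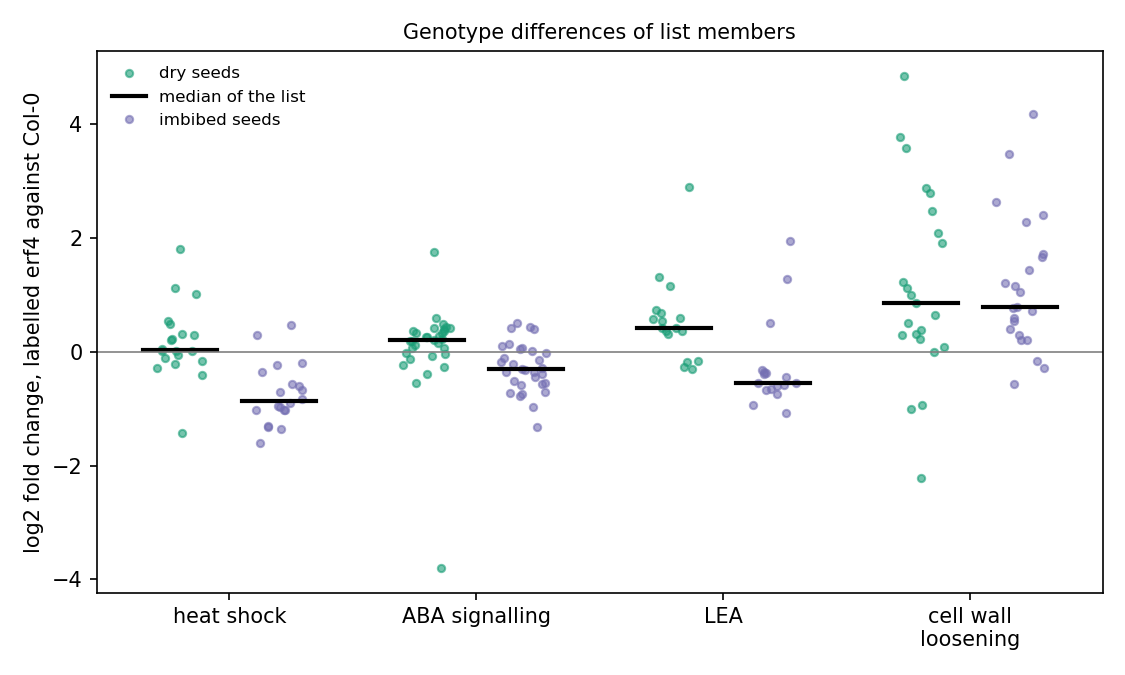
Log2 fold change of libraries labelled erf4 against Col-0 (vertical axis) of each tested member (points) of 4 gene lists (horizontal axis) in dry and imbibed seeds, with the list median (black bars). The heat shock median is 0.03 in dry and -0.88 in imbibed seeds and the ABA signalling median 0.20 and -0.30; points are fitted values, also for genes absent from a group.

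The third comparison asked what imbibition changed in Col-0. Transcripts that rose within 6 h included GA3OX1 and GA20OX3, which act in the synthesis of gibberellin, a hormone that promotes germination. The gibberellin list as a whole did not pass (camera adjusted p = 0.118). GA3OX1, which makes the active hormone, had no count in dry Col-0 and 2.33 ± 1.32 CPM after imbibition (SD, n = 3), at least 73.9-fold higher (edgeR adjusted p = 9.85e-05). GA20OX3 rose from 8.76 ± 2.34 to 124.1 ± 6.11 CPM (log2 fold change 3.82 ± 0.26 SE, edgeR adjusted p = 3.15e-07). The wall-modifying gene XTH16 rose from 0.13 ± 0.066 to 53.2 ± 11.6 CPM (8.67 ± 0.48, edgeR adjusted p = 1.18e-07) and the expansin gene EXPA10 from 0.494 ± 0.364 to 28.9 ± 9.88 CPM (5.81 ± 0.60, edgeR adjusted p = 1.22e-05). The albumin gene SESA5 fell from 5977.0 ± 1008.1 to 1252.1 ± 192.5 CPM (-2.26 ± 0.21, edgeR adjusted p = 2.02e-06) and the LEA gene ATECP31 from 5230.4 ± 647.8 to 1151.5 ± 199.1 CPM (-2.18 ± 0.22, edgeR adjusted p = 4.07e-06). DOG1 fell from 53.1 ± 9.76 to 19.0 ± 5.73 CPM (-1.49 ± 0.20, edgeR adjusted p = 4.98e-05), ABI5 from 687.9 ± 163.8 to 302.2 ± 35.4 CPM (-1.19 ± 0.24, edgeR adjusted p = 0.00101) and CAT3 from 4000.1 ± 205.7 to 2105.7 ± 222.3 CPM (-0.93 ± 0.16, edgeR adjusted p = 0.000364).

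The naming rule ranked genes by fitted log2 fold change, which puts genes without a count in a group first and is no bound for them, so that a measured rise such as that of XTH16 can be larger. The rises so named were all of genes without a count in dry Col-0. Against a floor of 3 counts over the group they were at least 294-fold for AT5G17760, 267.2-fold for the pumilio gene PUM9, 194.3-fold for the ATPase gene AATP1, 114-fold for XTH15, 94.1-fold for AT4G03292 and 73.9-fold for GA3OX1. The falls so named, to no count, were at least 294.6-fold for sks12, 289-fold for AT3G17060, 244.7-fold for AT5G28690, 231.6-fold for the sugar transporter gene STP11, 184.3-fold for AT1G76370 and 149.9-fold for AT1G30710. PUM9 and XTH15 overlap genes on the other strand. The pollen and tapetum markers fell with a median of -6.90, or -6.38 with genes absent from a group at their bound, and 31 of 36 members fell and 1 rose (31 and 2 adjusted over the list alone). The 23 not taken from the most changed genes had a median of -4.24. Among the gibberellin genes 13 rose and 7 fell of 28 (13 and 8 adjusted over the list alone; median 1.00, camera adjusted p = 0.118). The rises included RGA1 (2.68 ± 0.22, edgeR adjusted p = 8.46e-07) and RGL2 (from 18.6 ± 1.63 to 79.7 ± 5.85 CPM, edgeR adjusted p = 2.76e-06), which encode DELLA repressors of the gibberellin response.

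In all 9915 of 18897 genes were called in Col-0, 5148 higher and 4767 lower after imbibition (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these, 5365 changed at least 2-fold. With the preset correlation the ribosomal proteins rose (178 rose and 17 fell of 298, 182 and 19 adjusted over the list alone, camera adjusted p = 1.05e-10), as did cell wall loosening (13 rose and 2 fell of 23, 14 and 2 adjusted over the list alone, camera adjusted p = 0.000359) and the cell cycle genes (10 rose and 0 fell of 21, the same counts adjusted over the list alone, camera adjusted p = 0.0209). These calls were lost with adjusted p = 0.606 for cell wall loosening and adjusted p = 0.567 for the others with an estimated correlation. The median of the cell wall list was 2.98, or 2.3 with genes absent from a group at their bound. In the cell cycle list MCM2, of the replicative helicase, rose from 0.41 ± 0.3 to 4.69 ± 0.874 CPM (3.48 ± 0.50, edgeR adjusted p = 6.69e-05). The storage proteins (0 rose and 12 fell of 16, the same adjusted over the list alone, camera adjusted p = 0.000161) and the LEA proteins (1 rose and 10 fell of 17, the same adjusted over the list alone, camera adjusted p = 0.00347) fell. These calls were lost too, each with adjusted p = 0.567 with an estimated correlation.

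The remaining lists did not pass camera in Col-0, with adjusted p between 0.118 and 0.991. The ABA signalling genes moved both ways, with 11 that rose and 15 that fell of 31 (12 and 15 adjusted over the list alone), a median of -0.46 and a mean of 0.29 (camera direction lower, adjusted p = 0.984). OST1 rose from 10.9 ± 1.32 to 40.9 ± 4.04 CPM (1.90 ± 0.16, edgeR adjusted p = 1.22e-06) and ABI2 fell from 82.5 ± 10.1 to 27.7 ± 2.69 CPM (-1.57 ± 0.14, edgeR adjusted p = 1.35e-06). The heat shock genes were as divided, with 6 that rose and 6 that fell of 20 (the same adjusted over the list alone). HSFA9, a heat shock factor of seed maturation that overlaps a gene on the other strand, fell by 2.48 ± 0.34 on the log2 scale (edgeR adjusted p = 8.28e-05), and the small heat shock protein gene HSP17.6II rose by 2.03 ± 0.35 (edgeR adjusted p = 0.000396). The median, the mean and the test did not share a sign for the ABA signalling, clock, dormancy, endosperm, ethylene and flavonoid lists. In the clock list TOC1 fell from 169.3 ± 8.5 to 84.9 ± 4.21 CPM (edgeR adjusted p = 8.61e-06) and LHY rose (2.41 ± 0.34, edgeR adjusted p = 5.8e-05).

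The fourth comparison asked what imbibition changed in seeds labelled erf4. Genes of gibberellin synthesis, wall loosening and seed reserves were again among the called. GA3OX2, which makes active gibberellin, went from no count to 3.31 ± 1.21 CPM (SD, n = 3), at least 107.5-fold higher (edgeR adjusted p = 4.17e-05). XTH16 rose from 0.061 ± 0.106 to 43.9 ± 12.7 CPM (log2 fold change 9.39 ± 0.53 SE, edgeR adjusted p = 1.27e-07). EXPA8 rose from 1.19 ± 0.5 to 21.8 ± 6.7 CPM (4.18 ± 0.35, edgeR adjusted p = 9.45e-07). DOG1 fell from 30.6 ± 5.1 to 11.2 ± 0.648 CPM (-1.45 ± 0.21, edgeR adjusted p = 5.63e-05), ABI5 from 781.5 ± 257.6 to 206.4 ± 40.9 CPM (-1.92 ± 0.24, edgeR adjusted p = 2.4e-05) and CAT3 from 3740.5 ± 83.0 to 1868.1 ± 248.7 CPM (edgeR adjusted p = 0.000181). LEA7 fell from 2634.2 ± 435.8 to 514.1 ± 63.5 CPM (-2.36 ± 0.19, edgeR adjusted p = 7.6e-07) and HSP17.6A from 3569.9 ± 673.7 to 1011.9 ± 142.8 CPM (-1.82 ± 0.21, edgeR adjusted p = 9.39e-06).

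Ranked by fitted log2 fold change as above, the rises named were at least 245.5-fold for AATP1, 174.6-fold for PUM9, 135.7-fold for the ABA receptor gene PYL6 and 107.5-fold for GA3OX2. They were joined by bZIP44 (1 count over the dry group and 2672 over the imbibed group, edgeR adjusted p = 4.2e-08) and EXO (10.14 ± 0.62, from 6 to 10551 counts, edgeR adjusted p = 3.2e-07). The falls so named were at least 178.1-fold for AT3G14040, 169.7-fold for AT4G28140, 92.5-fold for AT4G18596, 62.5-fold for DES-1-LIKE and 61.0-fold for PMEI1, and CBL7 went from 146 counts to 1 (edgeR adjusted p = 0.000432). AT3G14040 shares 1646 bp with its copy AT3G07850 and AT4G18596 2338 bp with WAVE5. AT4G18596, DES-1-LIKE, LEA7 and PUM9 overlap genes on the other strand. Of 18897 genes 10496 were called, 5358 higher and 5138 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these, 5989 changed at least 2-fold. The pollen and tapetum markers had 27 members that fell and 1 that rose of 36 (the same adjusted over the list alone), with a median of -3.75, or -3.50 with genes absent from a group at their bound, and of -2.92 over the 23 not taken from the most changed genes.

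By list, the ribosomal proteins (193 rose and 17 fell of 298, 198 and 18 adjusted over the list alone, camera adjusted p = 6.1e-10), cell wall loosening (16 rose and 2 fell of 23, camera adjusted p = 4.56e-05) and the cell cycle genes (11 rose and 0 fell of 21, camera adjusted p = 0.00441) rose. Each of these calls was lost with adjusted p = 0.423 with an estimated correlation. The LEA proteins (0 rose and 15 fell of 17, camera adjusted p = 4.52e-07) and the storage proteins (0 rose and 13 fell of 16, 14 fell adjusted over the list alone, camera adjusted p = 4.56e-05) fell. These calls were lost too, each with adjusted p = 0.423 with an estimated correlation. Where no second pair of counts is given, those adjusted over the list alone were the same. Of the heat shock genes 3 rose and 11 fell of 20 (the same adjusted over the list alone, camera adjusted p = 0.0546). With the replicate number as a block within each genotype this list passed (adjusted p = 0.00425; adjusted p = 0.498 with an estimated correlation), as did ABA signalling (adjusted p = 0.0452; adjusted p = 0.422 with an estimated correlation). HSP101, which overlaps a gene on the other strand, fell by 2.03 ± 0.22 on the log2 scale (edgeR adjusted p = 7.44e-06). Of the ABA signalling genes 9 rose and 18 fell of 31 (9 and 19 adjusted over the list alone, camera adjusted p = 0.111), with HAI1, a phosphatase of the pathway, at 25.9 ± 5.97 CPM before and 2.26 ± 0.627 CPM after imbibition (-3.52 ± 0.32, edgeR adjusted p = 1.76e-06). The remaining lists had camera adjusted p between 0.114 and 0.956, and for the clock, dormancy, endosperm, lipid mobilisation and photosynthesis lists the median, the mean and the test did not share a sign.

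The 2 imbibition responses had 8156 called genes in common, 8148 of them in the same direction and 8 in opposite directions. A further 1759 were called in Col-0 alone and 2340 in the libraries labelled erf4 alone, which by itself shows no difference between the genotypes. Genes higher in both numbered 4150, where independent lists would share 1460, and genes lower in both 3998, where they would share 1296. Across the 18897 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.84.

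The last comparison tested directly whether the genotype difference, by the labels, changed with imbibition. No single gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0723, for IRT3, at 3.68 ± 0.51, and the pollen gene sks13, at 3.56 ± 0.49). Still, 1980 genes had an unadjusted p under 0.05 where chance gives 945, and DESeq2 called 191. IRT3 and sks13 were named here after their values were seen, and sks13 was low in imbibed seeds of both genotypes (0.996 ± 0.347 and 1.71 ± 0.57 CPM). With the replicate number as a block within each genotype 594 genes were called (163 with a larger and 431 with a smaller log2 difference after imbibition), with no filter on low counts 4, and without both libraries labelled erf4 replicate 1 there were 12. The count was 15 without the dry library labelled erf4 replicate 1, 2 without the imbibed library labelled erf4 replicate 3, and 1 without dry Col-0 replicate 2 or without the imbibed library labelled erf4 replicate 2. That block called IRT3 (edgeR adjusted p = 0.00211) and sks13 (edgeR adjusted p = 0.0346). DOG1 had an interaction of 0.03 ± 0.29 (edgeR adjusted p = 0.984), ABI5 of -0.73 ± 0.33 (edgeR adjusted p = 0.472, or 0.0346 with the block) and CAT3 of -0.08 ± 0.23 (edgeR adjusted p = 0.943).

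Among the lists, ABA signalling and response shifted down in the libraries labelled erf4 relative to Col-0 between the dry and the imbibed state (median -0.34, camera adjusted p = 1.69e-05; adjusted p = 0.0149 with an estimated correlation). With an estimated correlation it was lost without both libraries labelled erf4 replicate 1 or 3 (adjusted p = 0.0833 and 0.0564; 0.0393 without replicate 2). With the block within each genotype its adjusted p = 9.45e-05, and adjusted p = 0.435 with an estimated correlation. Of its 31 members 6 fell adjusted over the list alone, 0 were called by edgeR over all genes, 14 had an unadjusted p under 0.05 and DESeq2 called 2. ABI2 had an interaction of -0.97 ± 0.19 (edgeR adjusted p = 0.164, or 0.00204 with the block) and HAI1 of -1.66 ± 0.41 (edgeR adjusted p = 0.25, or 0.00651 with the block). The heat shock genes (7 of 20 adjusted over the list alone, 10 unadjusted and 4 by DESeq2, median -0.89, camera adjusted p = 5.68e-09) and the LEA proteins (3 of 17 adjusted over the list alone, 9 unadjusted and 3 by DESeq2, median -0.89, camera adjusted p = 1.84e-07) shifted down with the preset correlation. They had adjusted p = 0.0724 and adjusted p = 0.181 with an estimated correlation. The pollen and tapetum markers had a positive median of 1.84 (16 of 36 adjusted over the list alone, 0 by edgeR over all genes, 20 unadjusted and 11 by DESeq2, camera unadjusted p = 3.18e-19, or 0.00285 with an estimated correlation), and the 23 not taken from the most changed genes one of 1.06 (quartiles 0.01 and 3.44, camera unadjusted p = 3.19e-05, or 0.0191 with an estimated correlation). This list was chosen for its fall in dry seeds, and only 8 of the 36 reached 1 CPM in imbibed Col-0, so that these values are not evidence apart from the dry difference. The other fixed lists had 0 members called by edgeR, 0 to 38 unadjusted, 0 to 5 by DESeq2 and camera adjusted p between 0.354 and 0.978, and for the cell wall, clock, flavonoid, gibberellin, reactive oxygen and ribosomal lists the median, the mean and the test did not share a sign.

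The genotype calls of dry and imbibed seeds, which share no library, had 3 genes in common, RPL18AA, IRT3 and AT1G75945, all higher in libraries labelled erf4 in both states. Independent lists of that size would share 0.0156 genes (one-sided Fisher's exact test, p = 1.35e-07). The 2 comparisons were not fully independent, since dry and imbibed libraries labelled erf4 of the same number deviated together from their group means (r of 0.34, 0.34 and 0.35 across genes), which neither value takes into account. No lower call was shared between the 109 genes in dry seeds and the 1 gene, HEI10, in imbibed seeds, where independent lists would share 0.0058. With none shared the one-sided Fisher's exact test gives p = 1 in any case and decides nothing. HEI10 lay lower in dry seeds under each alternative fit (log2 fold change -0.97 to -0.67) and was called in 4 of 23. In imbibed Col-0, 51 of the 109 genes stood under 5% of their dry Col-0 level. So did 303 of all 18897 genes tested and 0 of the 98 genes called higher in dry seeds. The dry Col-0 level enters both measures. DESeq2 shared 45 lower calls. Of the 207 genes called in dry seeds by edgeR, 147 had the same sign in imbibed seeds, 66 of these with an unadjusted p under 0.05. Across the 18897 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.27, which does not allow for that pairing either. The overlap was 5 genes with the replicate number as a block, 107 with DESeq2, 88 without both libraries labelled erf4 replicate 2, 7 without the dry and 10 without the imbibed library labelled erf4 replicate 2.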

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

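The tests of Col-0 seeds among those labelled erf4, of carried-over pollen, of the library suffix, of the pollen markers not seen beforehand, of a single pair of libraries and of a shift in proportion to the Col-0 response, and the splits of the samples, were chosen only after the results they bear on had been seen. The test of GC content and gene length and the correlation with the response to imbibition were chosen before. For 3 lists the genotype difference itself changed between dry and imbibed seeds by the test of that difference (camera with the preset correlation): ABA signalling (adjusted p = 1.69e-05), heat shock (adjusted p = 5.68e-09) and LEA proteins (adjusted p = 1.84e-07). With an estimated correlation the call of ABA signalling held (adjusted p = 0.0149, but 0.0833 and 0.0564 without both libraries labelled erf4 numbered 1 or 3, and 0.435 with the block within each genotype), and those of heat shock (adjusted p = 0.0724) and LEA proteins (adjusted p = 0.181) were lost. The pollen markers, a list written afterwards, passed the same test (unadjusted p = 3.18e-19). As the list was chosen for its fall in dry seeds and its members were low in imbibed seeds of both genotypes (summing to 50.0 and 47.5 CPM), a positive value was largely set in advance, also over the 23 markers not seen beforehand (median 1.06, unadjusted p = 3.19e-05), and does not show a change of the genotype difference apart from the fall in dry seeds. The LEA median was 0.42 in dry and -0.55 in imbibed seeds.

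ERF4 stood at 109.0 and 83.3% of the Col-0 mean in the dry and imbibed libraries labelled erf4 replicate 3, against 27.7 and 9.3% in replicate 1. GC content and gene length bias is argued against as the cause of the low values, since 200 genes matched on both and on level lay above ERF4 by at least 1.88 (log2) in the median in both libraries of replicate 1. Col-0 seeds in place of those of replicate 3, or mixed into them at a share that would give these ERF4 levels, are argued against. Over genes called without this replicate, its libraries lay 0.81 of the way from Col-0 to the other libraries labelled erf4 in dry seeds (69 genes, quartiles 0.64 and 0.98). In imbibed seeds the value was 0.96 (6 genes, quartiles 0.61 and 0.99, 4 of them nearer the other libraries labelled erf4). The same position was 0.57 and 0.56 in dry replicates 1 and 2 (384 and 368 genes), and 1.03 (4 genes) and 0.42 (384 genes, 144 of them nearer the other libraries labelled erf4) in imbibed replicates 1 and 2, so that Col-0 seeds mixed into replicate 2, with ERF4 at 64.3 and 39.2%, stay open, as does a smaller share in replicate 3. Single genes went both ways in the imbibed library of replicate 2. RPL18AA (15.92 CPM) and AT1G75945 (16.83 CPM) stood higher there than in replicates 1 and 3. HEI10 (4.04 CPM) lay near those replicates (3.27 and 3.74) and far from Col-0 (13.03 to 13.73). IRT3 lay lower (24.48 CPM, against 46.81 and 38.73). These 4 genes are too few to settle whether Col-0 seeds were mixed in. Transcript made in spite of the mutation and segregation at ERF4 stay open and may apply, as neither was tested.

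The pollen markers lay lower in the dry libraries labelled erf4 and low in all imbibed libraries. Pollen or anther material carried over with the dry seeds stays open: the 23 tested markers that had not been seen beforehand had a median of -1.56 (quartiles -2.6 and -0.76, 21 of 23 negative, 7 called), so the pattern reached beyond the genes that prompted the list, but a genotype effect on transcripts of pollen type predicts the same value. Of the 36 tested markers none stands in a fixed list, 32 reached 1 CPM in dry Col-0 and 25 in the dry libraries labelled erf4, and 8 in imbibed Col-0, so seeds themselves may express part of them. The library suffix as the whole cause is argued against, though with small arms: the median difference was -2.09 within the b libraries (2 Col-0 and 1 labelled erf4) and -2.5 within the r libraries (1 and 2), and the markers summed to at least 539.0 CPM in each dry Col-0 library and at most 163.7 CPM in each dry library labelled erf4. That genotype effect was not tested apart from carry-over, and the imbibed seeds had been wetted, which the data cannot separate from loss of such material.

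The heat shock and ABA signalling lists lay lower in the imbibed libraries labelled erf4 and, in the median, not in the dry ones. A single pair of libraries is argued against for heat shock. Its median was -0.74, -0.96 and -0.92 without number 1, 2 or 3 labelled erf4 (upper quartiles -0.54, -0.46 and -0.48). The ABA signalling median was carried by no 1 pair either, at -0.24, -0.30 and -0.37 in that order against -0.30 with all libraries. Its members went both ways, with 21, 22 and 23 of 31 negative (upper quartiles 0.01, 0.06 and 0.02). A single pair therefore stays open for part of them. The camera tests do not separate the lists. The largest camera adjusted p was 0.000584 with the preset correlation. Both calls were lost with an estimated one (camera adjusted p 0.107 to 0.153 for heat shock and 0.0829 to 0.118 for ABA signalling). Across genes, which are not independent replicates, their difference from Col-0 correlated with the Col-0 response from other libraries at a mean r of 0.21 (0.19, 0.26 and 0.19, mean slope 0.081), over the limit of 0.2 set beforehand for further progress through imbibition; but single libraries labelled erf4 gave 0.14, 0.2 and 0.19, Col-0 libraries set against each other -0.1, 0.14 and -0.04, and dry seeds, which had received no water, 0.32. A shift in proportion to that response, at the slope seen across genes, is argued against for the heat shock list. Of its 20 members 6 rose and 6 fell in Col-0 (median 0.11). With the trend removed from every gene its median stayed at -0.85 (quartiles -1.12 and -0.44). As the mean slope was 0.081, removing the trend could move a median little, so the removal by itself decides little. The ABA signalling median went from -0.30 to -0.39 (quartiles -0.64 and 0.01), further from 0. A shift at that small slope thus did not account for its lower median. Its members went both ways, with 22 of 31 negative before the removal and 23 after. Progress of another form and, untested, a direct effect of the genotype stay open for both lists.

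With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 4 comparisons only 1 split, the real one, called as many genes as the real one. The real and the highest other counts were 207 and 1 in dry seeds, 4 and 0 in imbibed seeds, 9915 and 0 for imbibition in Col-0, and 10496 and 0 in libraries labelled erf4. Every other split mixed libraries of both real groups on each side. Differences between the real groups thus became spread within the sides, which by itself holds the other counts low. For the interaction the real split called 0 genes by edgeR (1980 at an unadjusted p under 0.05, 191 by DESeq2, and 594 with the replicate number as a block within each genotype, chosen afterwards) and the highest other 0. With a real count of 0 all 60 splits drawn call as many whatever the data, and they did not keep the pairing of the libraries labelled erf4, so they decide nothing.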

How the results depend on the processing

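The fits without both libraries labelled erf4 of 1 number and with a block within each genotype were chosen only after the data had been seen. None of the 235 calls of named genes and 33 list calls changed direction under an alternative run for it. The sign of 7 values that were not called did, in 22 fits in all, and the cause was not tested. ABI5 in dry seeds (0.18) was -0.02 with the suffix covariate and -0.11 without both libraries labelled erf4 numbered 2, with -0.11 to 0.4 without 1 library. ERF4 on imbibition in Col-0 (0.35) was -0.15 with the suffix covariate, and in libraries labelled erf4 (-0.25) it ran from -1.1 to 0.31 without 1 library. In the interaction DOG1 (0.03) was -0.02 with the suffix covariate and -0.09 without both numbered 3, and AT3G15200 (0.05) was -0.02 and -0.1 without both numbered 1 or 3. Without 1 library they ran from -0.12 to 0.29 and from -0.04 to 0.17, the list members FWA (-0.34) from -0.65 to 0.06 and FER4 (0.29) from -0.01 to 0.51. With RLE size factors, 1 CPM in 6 libraries and nuclear genes only, each count of calls stayed within 1.5 times its reported value (dry seeds 204, 197 and 222), and RLE moved the median log2 fold change of all genes by less than 0.1. Of 235 calls of named genes in a comparison, RLE kept 235, no filter 231, the suffix covariate 230, DESeq2 234, a log2 fold change of at least 1 205, an adjusted p under 0.01 213, the 2 groups alone 222 of 232, and leaving out 1 library 220 to 234. Of 33 list calls RLE and nuclear genes kept 33, the suffix 32, leaving out both libraries labelled erf4 numbered 1, 2 or 3 kept 27, 32 or 31, and an estimated correlation 6. The list calls include those of the pollen and tapetum markers, taken at an unadjusted p. Of the fixed lists, an estimated correlation kept only heat shock and ABA signalling in imbibed seeds and ABA signalling in the interaction.

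The counts of calls that moved by over 1.5 times were as follows, and except where fewer libraries or a stricter limit applied the cause was not tested. In dry seeds (207) the suffix covariate gave 464, the 2 groups alone 114, DESeq2 936, a log2 fold change of at least 1 136, an adjusted p under 0.01 37, and leaving out both libraries labelled erf4 numbered 1, 2 or 3 gave 384, 368 or 69. In imbibed seeds (4) no filter gave 18, DESeq2 527 and the fit without both numbered 2 386. A log2 fold change of at least 1 left 5365 of the 9915 calls in Col-0 and 5989 of the 10496 in libraries labelled erf4. The interaction (0 by edgeR, 1980 at an unadjusted p under 0.05) had 4 calls with no filter, 12 without both numbered 1 and 191 with DESeq2. The overlap of genotype calls (3) was 88 without both numbered 2 and 107 with DESeq2. Leaving out 1 library gave 41 to 284 calls in dry seeds, 4 to 47 in imbibed seeds, 8330 to 10369 in Col-0, 9422 to 10584 in libraries labelled erf4, 0 to 15 for the interaction and 2 to 10 for the overlap.

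With the replicate number as a block there were 204 calls in dry seeds, 6 in imbibed seeds, 9836 in Col-0, 10392 in libraries labelled erf4, 0 for the interaction and 5 in the overlap; 232 of 235 named calls and 32 of 33 list calls were kept. Col-0 libraries correlated with their own number at 0.11, 0.07 and 0.21, each best with its own, a hint from the data only. The block within each genotype gave 11352 calls in Col-0, 11860 in libraries labelled erf4 and 594 for the interaction, and kept 207 of 208 named calls and 15 of 16 list calls (cell cycle in Col-0 at adjusted p = 0.054). It newly called 17 named results, ERF4 on imbibition in libraries labelled erf4 (-0.48, edgeR adjusted p = 0.0446) and 16 in the interaction. IRT3 and HEI10, which the naming rule did not take in the interaction, were called there too (edgeR adjusted p = 0.00211 and 0.039). The interaction of IRT3 passed in 6 of 23 alternatives (adjusted p from 3.72e-09 to 0.298). A level of 3 counts in a library corresponded to 0.070 to 0.094 CPM before TMM scaling, and which genes depth limits was not tested.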

Other observations

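The averages over both seed states and the counts by chromosome were chosen only after the data had been seen. Averaged over dry and imbibed seeds, 449 of 18897 genes were called, 276 higher and 173 lower in libraries labelled erf4 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), a direction that rests on the labels. This fit took all libraries as independent, although dry and imbibed libraries labelled erf4 of a number deviated together. Neither this count nor the edgeR adjusted p values that follow allow for that. The naming rule did not cover this fit, and other genes with a smaller adjusted p than some of those named were passed over. ABCB9, a transporter gene of the ABC family, lay lower by a log2 fold change of -2.21 (edgeR adjusted p = 0.00115) and PTR5, a peptide transporter gene, by -1.41 (edgeR adjusted p = 0.00486). ANNAT1, an annexin gene that overlaps PUM9 on the other strand, lay lower by -1.23 (edgeR adjusted p = 0.00296). ASN3, an asparagine synthetase gene, lay higher by 1.21 (edgeR adjusted p = 0.00696), the myrosinase gene TGG1 by 1.49 (edgeR adjusted p = 0.0101) and the pectin methylesterase gene PME3 by 0.91 (edgeR adjusted p = 0.0116). With the dry and imbibed library of a number averaged first, 5 genes were called: AT1G75945 (6.49), RPL18AA (2.75), IRT3 (3.97), AT2G17500 (-0.99) and ABCB9 (-2.19). PTR5, ANNAT1, ASN3, TGG1 and PME3 were not among them.

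The 4 genes called in imbibed seeds all lie on chromosome 1, which holds 4952 of the 18897 genes tested. The calls in dry seeds numbered 43, 34, 52, 28 and 50 on chromosomes 1 to 5, of 4952, 2899, 3742, 2826 and 4372 genes tested.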
